A study of Mus musculus with 6 samples.

How the data were processed

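Gene expression was measured on 6 single-colour Affymetrix whole-transcript arrays. Each array held biotin-labelled cDNA made from 100 ng of total RNA of sorted mouse T cells, per the labels' protocols. The arrays fall into 2 groups of 3, Tregs recovered from MHC II-competent recipients and Tregs recovered from MHC II-deficient recipients. The labels name the replicates of each group as biological and number them 1 to 3. They do not say whether a replicate is a single recipient or a pool, so the p-values measure the spread between these 3 preparations per group, whatever they hold. Below, the arrays are called competent 1 to 3 and deficient 1 to 3.

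The deposited table gives 1 log2 value per array for each of 28101 rows. Per the submitters' processing notes, the authors used the R package affy and robust multi-array averaging (RMA), which corrects the background, sets the arrays to a common distribution and summarises the probes of each row. The log base of the deposited values is not stated. It was taken as 2, the base of RMA output, and the values, from 2.40 to 13.3 over the 6 arrays, fall in the range of such output. The software versions, the annotation and the genome build were not given in the sources used here, so no coordinates are reported. The array medians lay between 6.11 and 6.25. The scanner files and detection calls were not used here.

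Rows were named through the platform's annotation, with symbols updated by Entrez identifier from a table of the GRCm38.p6 assembly that was used for names only. Of the 28101 rows, 21640 were paired with 1 gene symbol, 1321 with several and 5140 with none. The identifier was found for 21553 of the rows with 1 symbol, and the other 87 kept the symbol of the platform. Rows with several symbols or none entered no named result. No row was marked as a control and none was left out for that reason. The 21640 rows hold 19937 genes, of which 954 have more than 1 row. Such a gene was represented by its row with the highest mean over the 6 arrays. Genes whose mean lay under 5.205, the 25th percentile of all gene rows, were left out. This removed 4900 genes and left 15037. An array row can also bind transcripts of near-identical copies, so values of Ifit3 and Ifit3b, of Iltifb, a copy of the interleukin-22 gene, of Klrc1 and of the Ifi200-type genes are uncertain as to which copy they measure. Some list members are not reported here.

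The comparison is MHC II-deficient minus MHC II-competent, in log2 units. It was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, two-sided, no covariate), on the deposited values without further normalization. The fit has 4 residual degrees of freedom, and 9.40 with the prior. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called past the threshold. The errors given with differences are limma's standard errors, and group values are means with SD over 3 arrays.

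The 23 gene lists were fixed before the data were examined: Treg identity, Treg suppressive effectors, TCR-induced genes, TCR complex and proximal signalling, naive and quiescent T cells, activated Tregs and tissue homing, cell cycle, glycolysis, cholesterol and fatty acid synthesis, mitochondrial respiration, nucleolus and ribosome biogenesis, IL-2 and STAT5 targets, the TNF receptor family with NF-kappaB, apoptosis regulators, interferon-stimulated genes, helper T cell lineages, conventional CD4 T cells, heat shock, MHC class II presentation, B cells, myeloid and dendritic cells, CD8 T and NK cells, and erythroid cells with platelets. Each list was set against the other tested genes with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 23 lists. Camera with a correlation estimated for each list and fry, which asks whether the genes of a list move one way on balance, were run as alternatives.

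The named genes were also set by a rule fixed before the data were examined. Among genes past the threshold whose groups do not overlap, it took the 12 with the largest increases and the 12 with the largest decreases, then up to 4 called members of each list by smallest p, and a fixed set of genes whatever their values (Foxp3, Il2ra, Ctla4, Ikzf2, Tnfrsf18, Nr4a1, Egr2, Cd5, Klf2, H2-Ab1 and Cd74 among those tested). The rule named 66 tested genes. Genes named in addition are said to have been chosen after their values were seen.

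The fit and the list tests were first tested on simulated values for the same 15037 genes with the same means and spreads. In this comparison of 3 against 3 arrays, 22 of 50 genes changed by a log2 size of 0.5 were recovered, 44 of 50 at 1, 49 of 50 at 1.5 and 49 of 50 at 2. Of the 178 genes called, 10 had been left unchanged. The 1 list that had been shifted was called, and 0 others were. The simulated noise was drawn independently for each gene, so list calls were not checked under correlation between genes. In the real arrays the estimated correlation was 0.39 for the interferon-stimulated genes and 0.28 for the cell cycle list.

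Alternatives fixed beforehand were no filter, a filter at the median, quantile normalization, median centring, a trended robust prior, array weights, the replicate number as a block, each array left out in turn, the mean of the rows of a gene, all rows of the table, an adjusted p under 0.1, a minimum of 1.5-fold, and for the lists an estimated correlation, fry and lists without shared genes. After the data had been examined, a fit with a myeloid marker score as a covariate was added. The score of an array is the mean of the 17 tested genes of the myeloid and dendritic cell list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.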

Results

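The series profiled mouse regulatory T cells (Tregs), the CD4+ T cells that restrain immune responses and depend on the transcription factor Foxp3. T cells of wild-type C57BL/6 mice were transferred into CD3ε-deficient recipients, which have no T cells of their own. The recipients either expressed MHC class II (MHC II-competent), the molecules that present peptides to the T cell receptor (TCR) of CD4+ T cells, or lacked it (MHC II-deficient). On day 5 the CD4+ TCRβ+ CD25+ cells were isolated with magnetic beads and a cell sorter, with lymph nodes and spleen given as the tissue of origin. There were 3 arrays per group, each with 28101 log2 values and a median between 6.11 and 6.25. The comparison asks which transcripts of the sorted CD25+ cells differ after 5 days in MHC II-deficient against MHC II-competent recipients.

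In the CD25+ cells sorted from MHC II-deficient recipients many interferon-stimulated genes rose, and genes of activated, tissue-homing Tregs and of the cell cycle fell. The values are of the whole sort and do not show which of its cells changed. Of the 18 interferon-stimulated genes tested, 16 rose, with Oasl2 4.99-fold higher (log2 difference 2.32, SE 0.13, 3 arrays per group). Of the 18 activation and homing genes, 10 fell, among them Itgae, which encodes the αE integrin CD103, by 1.18 on the log2 scale (SE 0.15) and the chemokine receptor gene Ccr8 by 1.53 (SE 0.25). Of 23 cell cycle genes 8 fell, but 0 did without competent 2 or deficient 1. For these 3 lists the adjusted p = 0.085, 0.075 and 0.15 with an estimated correlation. Myeloid markers had a median difference of 0.71 (0.42 to 0.88 with 1 array left out), and with their score as a covariate 11, 1 and 0 genes of the 3 lists passed. The list medians were then 1.06, -0.57 and -0.42, against 1.10, -0.52 and -0.42 without it, while the median SE went from 0.12 to 0.18, 0.17 and 0.17 with 3 residual degrees of freedom. Foxp3 itself stood at 9.77 ± 0.09 (SD, n = 3) in the MHC II-deficient and 9.82 ± 0.05 (SD, n = 3) in the MHC II-competent group. The difference of -0.06 had a 95% interval from -0.27 to 0.16 and an adjusted p of 0.80, and its sign turned under quantile normalization (0.02).

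Over all 15037 genes tested, 507 (3.37%) were past the threshold of limma's test, 201 higher and 306 lower in the MHC II-deficient group. Quantile normalization gave 230 higher and 230 lower. At least 1.5-fold differences were found for 142 of the higher and 187 of the lower genes, and at least 2-fold differences for 50 and 34. The groups did not overlap for any of the 507 genes, nor for 3654 of the tested genes (24.3%), where chance gives 10% for 3 against 3 arrays. The median log2 difference over all tested genes was 0.02. The first principal component, with 45.7% of the variance, separated the groups. With 1 array left out the count was 249 (without competent 1), 173 (competent 2), 159 (deficient 1), 213 (deficient 2) and 320 (deficient 3). Without competent 3 it was 708, of which 486 were lower in the MHC II-deficient group. With the myeloid marker score as a covariate, an alternative added after the data had been examined, 102 genes passed, 80 of them among the 507.

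**Figure D1:**
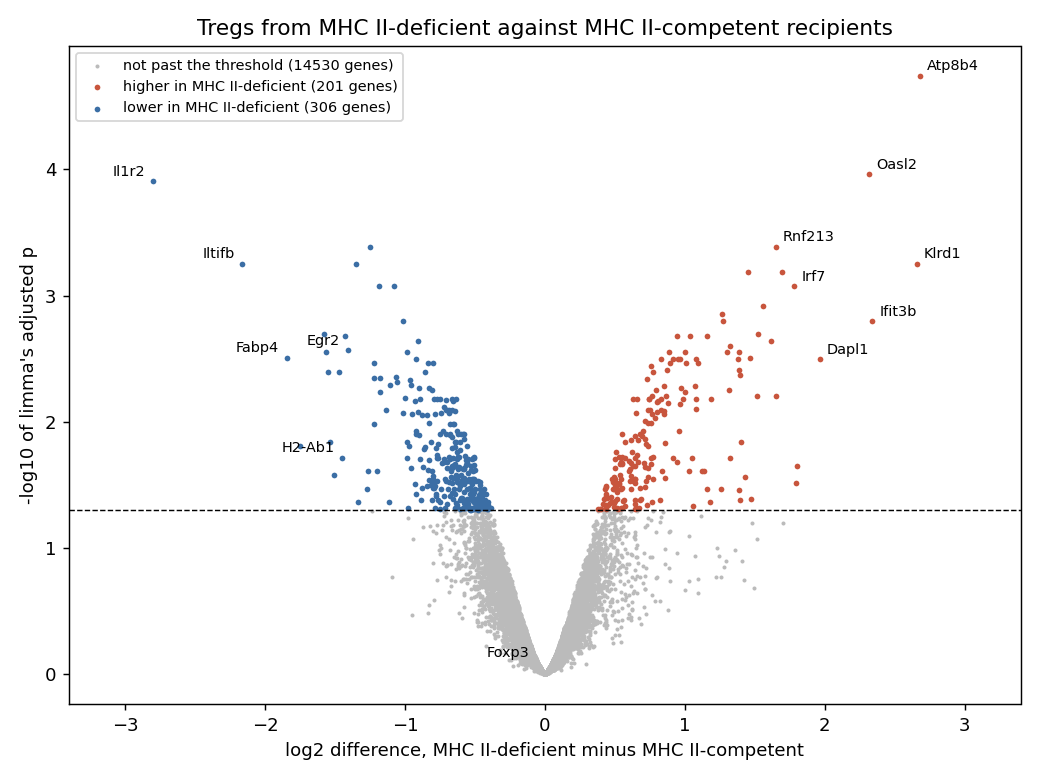
Each point is 1 of 15037 tested genes, with the log2 difference (MHC II-deficient minus MHC II-competent, 3 arrays per group) on the horizontal axis and the negative log10 of limma's adjusted p on the vertical axis; the dashed line marks an adjusted p of 0.05. The 201 higher genes are red and the 306 lower genes blue, with Atp8b4 (2.68) and Il1r2 (-2.80) at the ends and Foxp3 near the origin.

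The gene with the largest increase was Atp8b4 (row 10487208), which encodes a phospholipid flippase. It rose from 6.20 ± 0.17 to 8.88 ± 0.10 (SD, n = 3), a 6.42-fold difference (log2 2.68, SE 0.11, adjusted p = 1.82e-05). Klrd1 (row 10542214), which encodes the CD94 receptor of NK cells and some T cells, rose as well (log2 2.66, SE 0.21, adjusted p = 0.00056). The other 10 of the 12 largest increases were Ifit3b, Oasl2, Dapl1, Klrc1, Mx2, Irf7, Ms4a4c, Ifi213, Rnf213 and Ifit3, between 1.62 and 2.34 on the log2 scale. The largest decrease was that of Il1r2 (row 10345752), the decoy receptor for interleukin-1, from 9.28 ± 0.36 to 6.48 ± 0.13 (SD, n = 3). It fell by 2.80 on the log2 scale (SE 0.17, adjusted p = 0.00012). Iltifb, a copy of the interleukin-22 gene, fell by 2.16 (SE 0.16) and Fabp4, which encodes a fatty acid binding protein, by 1.85 (SE 0.21). The remaining decreases among the 12 largest were Ermn, Atp6v0d2, Sccpdh, Cpd, Ccr8, Serpinb1a, Penk, H2-Ab1 and Il10, from -1.75 to -1.42. The lower group mean lay under the filter value of 5.205 for Klrd1 (4.67), Iltifb (4.70) and Ermn (5.20), so the sizes and ranks of these 3 differences are uncertain. It lay near that value for Serpinb1a (5.30), Il10 (5.31), Fabp4 (5.41), Sccpdh (5.52) and H2-Ab1 (5.70), whose sizes and ranks are less sure as well. Among these 24 genes, the adjusted p exceeded 0.05 without at least 1 of the arrays for Mx2 (competent 1 and 2, deficient 1 and 3, highest 0.12), Serpinb1a (competent 2 and all 3 deficient arrays, highest 0.12), Klrc1 (competent 2, deficient 1 and 3, highest 0.10), Ermn (competent 1 and 2, deficient 2, highest 0.088), Ccr8 (competent 1 and 2, highest 0.086) and H2-Ab1 (competent 1, deficient 1 and 3, highest 0.077). With the myeloid score as a covariate the calls of Dapl1 (log2 1.96 to 1.83, SE 0.23 to 0.34, adjusted p = 0.053), Mx2 (1.79 to 2.0, SE 0.36 to 0.53, adjusted p = 0.13) and Klrc1 (1.81 to 1.49, SE 0.33 to 0.48, adjusted p = 0.19) ended. Each SE grew, and the differences of Dapl1 and Klrc1 also shrank.

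Markers of macrophages were followed as a measure of other cells in the sorts. The mean of the 17 tested genes of the myeloid and dendritic cell list was 6.44, 6.70 and 5.97 in the MHC II-competent and 7.27, 7.09 and 6.63 in the MHC II-deficient arrays. The list's median log2 difference was 0.71, with 13 genes higher and 4 lower. It was 0.42 without deficient 2, 0.46 without competent 3, 0.30 with no filter on low values and 1.22 with a filter at the median, and the highest with 1 array left out was 0.88 (without competent 2). Adgre1, which encodes the macrophage antigen F4/80, was its 1 member past the threshold over all genes (log2 1.39, SE 0.29), while adjusted over the list alone 9 members were higher and 2 lower. Genes chosen after their values were seen that did not pass were the complement genes C1qa (log2 1.36, SE 0.39, adjusted p = 0.10), C1qb (1.07, SE 0.32) and C1qc (1.41, SE 0.44), the adaptor gene Tyrobp (1.52, SE 0.41, adjusted p = 0.085), Mpeg1 (1.42, SE 0.52, adjusted p = 0.18), Csf1r (0.89, SE 0.33, adjusted p = 0.18) and Cst3 (-0.28, SE 0.10, adjusted p = 0.18). Camera called the list (adjusted p = 0.00058), with an adjusted p = 0.38 with an estimated correlation and 0.18 by fry. The call of Adgre1 ended without any of 5 arrays (all but deficient 3, highest adjusted p 0.11), and without deficient 3 the list had 3 higher members past the threshold. Without competent 3 it had 1, which was lower, and C1qa passed without deficient 3 (adjusted p = 0.034). Without competent 3 the differences of C1qc (0.88), Tyrobp (0.96), Mpeg1 (0.91) and Csf1r (0.58) were smaller. With the replicate number as a block, 8 members were past the threshold, although the labels do not say whether the numbers pair the arrays. Among the 8 were C1qa (adjusted p = 0.0021), C1qb (0.014), C1qc (0.0021), Tyrobp (0.0027), Mpeg1 (0.0064) and Csf1r (0.030). Array weights gave 3 higher and 1 lower, and quantile normalization, median centring and the trended robust prior 0. Once the mean of these genes was a covariate, they lost most of their difference by construction (list median 0.06, C1qa 0.08, C1qc 0.02, Tyrobp 0.24), and the sign turned for Mpeg1 (-0.28) and Csf1r (-0.15).

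Among the MHC class II genes 1 fell. H2-Ab1 (row 10444291), which encodes the β chain of the class II molecule I-A, was 2.74-fold lower in the sort from MHC II-deficient recipients, at 5.70 ± 0.17 against 7.15 ± 0.62 (SD, n = 3). It fell by 1.45 on the log2 scale (SE 0.26, adjusted p = 0.019). Of the 8 tested genes of the list it was the 1 past the threshold, and adjusted over the list alone 1 gene was higher and 1 lower. H2-Aa (log2 -1.09, SE 0.39, adjusted p = 0.17) and H2-Eb1 (-0.33, SE 0.13, adjusted p = 0.22), both chosen after their values were seen, did not pass. H2-DMa (0.50, SE 0.25, adjusted p = 0.32), chosen likewise, did not pass, and its value was 0.16 without competent 3 and turned its sign with the myeloid score as a covariate (-0.14). Without competent 2, H2-Aa stood at -0.57 and H2-Eb1 at -0.21, and without competent 3 H2-Aa stood at -1.57. Cd74, the invariant chain that assembles with class II, stood at a log2 difference of 0.77 (SE 0.23, adjusted p = 0.12), and at 0.09 with the myeloid covariate. The list was not called (median -0.11, with -0.25 without competent 3 and -0.049 without competent 2, adjusted p = 0.33, from 0.0022 with the myeloid score as a covariate to 0.78 over the alternatives). The call of H2-Ab1 ended without competent 1 (adjusted p = 0.053), deficient 1 (0.077) or deficient 3 (0.051). H2-Aa passed without competent 3 (0.019) and with the replicate block (0.043), and Cd74 without competent 2 (0.047) and with that block (0.022).

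**Figure D2:**
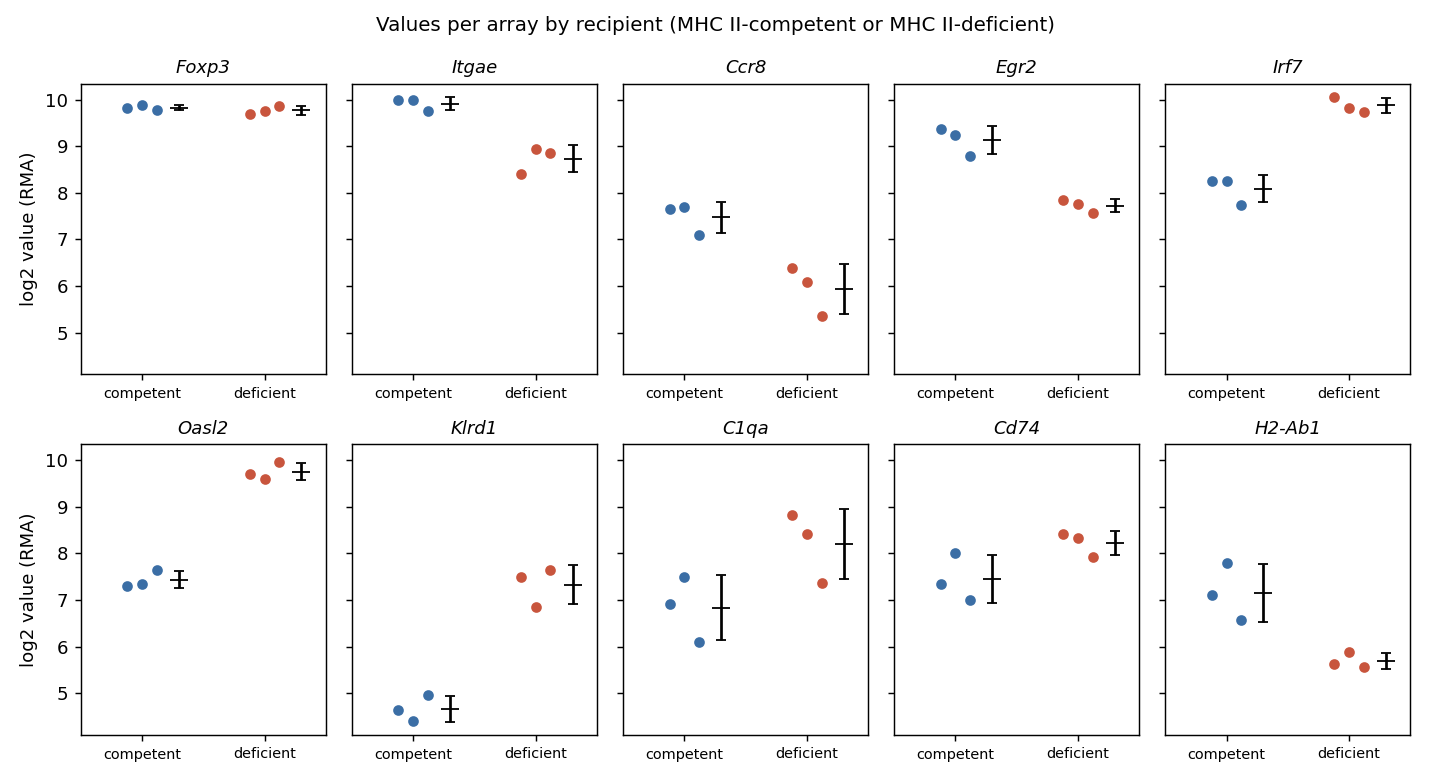
Points are the log2 RMA values of the 3 arrays per group for 10 genes (blue, MHC II-competent; red, MHC II-deficient recipients), with the group mean and SD beside them in black. Foxp3 lies at 9.82 and 9.77, Itgae, Ccr8, Egr2 and H2-Ab1 are lower and Irf7, Oasl2 and Klrd1 higher in the MHC II-deficient group, and the ranges of C1qa overlap.

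All 18 tested interferon-stimulated genes, which cells induce in response to interferons, lay higher in the MHC II-deficient group, and 16 of them rose (18 adjusted over the list alone). The median log2 difference was 1.10. Besides Oasl2, the antiviral gene Ifit1 was 2.74-fold higher (log2 1.45, SE 0.12, adjusted p = 0.00065), Irf7, a transcription factor of the interferon response, 3.44-fold (1.78, SE 0.15, adjusted p = 0.00085), and Stat2, which carries the signal of the type I interferon receptor, 2.40-fold (1.26, SE 0.12, adjusted p = 0.0014). The 2 members that did not pass, named after their values were seen, were Irgm1 (0.76, SE 0.18, adjusted p = 0.060) and Irf9 (0.41, SE 0.14, adjusted p = 0.15). Irgm1 passed without competent 3 (0.039), under quantile normalization (0.039), array weights (0.039), the trended robust prior (0.049) and the replicate block (0.028). Camera called the list with an adjusted p of 5.00e-29, and the adjusted p = 0.085 with an estimated correlation. The myeloid list had a median of 0.71 (13 genes higher, 4 lower, 1 past the threshold), and 11 of the 18 genes passed once their score was a covariate.

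Activation and homing genes of Tregs were lower as a group. Of 18 tested, 10 fell and 0 rose (14 lower and 1 higher adjusted over the list alone), with a median of -0.52. Besides Itgae (adjusted p = 0.0045) and Ccr8 (0.015), the chemokine receptor gene Ccr2 fell by 1.14 (SE 0.16, adjusted p = 0.0080), S100a4 by 0.79 (SE 0.11), Icos, which encodes a costimulatory receptor, by 0.70 (SE 0.13) and the nuclear receptor gene Rora by 0.60 (SE 0.09). Camera gave an adjusted p of 7.07e-11, and the adjusted p = 0.075 with an estimated correlation. Beside a myeloid median of 0.71, 16 of the 18 lay lower and 1 passed once the myeloid score was a covariate, as the list median went from -0.52 to -0.57 and the median SE from 0.12 to 0.17. The count of lower genes was 5 without competent 1, 4 without competent 2, 6 without deficient 1 and 4 without deficient 2. The call of Icos ended without competent 1, competent 2 or deficient 2 (highest adjusted p 0.089) and that of Rora without deficient 1 or 2 (0.059).

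Among 21 genes of Treg identity, 4 fell and 0 rose (9 lower and 1 higher adjusted over the list alone). They were Penk, the preproenkephalin gene (-1.47, SE 0.18, adjusted p = 0.0040), Tigit, an inhibitory receptor gene (-1.22, SE 0.19, adjusted p = 0.010), Itgae, and Nrp1, the neuropilin-1 gene (-0.58, SE 0.13, adjusted p = 0.048). The genes Il2ra (-0.27, SE 0.11), Ctla4 (-0.33, SE 0.11) and Ikzf2 (-0.29, SE 0.11), which encode CD25, CTLA-4 and Helios, did not pass (adjusted p = 0.22, 0.17 and 0.20), and Il2ra stood at -0.17 without competent 2 and Ikzf2 at -0.19 without deficient 2. Tnfrsf18, which encodes GITR, differed by -0.00 (SE 0.19, adjusted p = 0.99), at 10.87 ± 0.10 in the MHC II-deficient and 10.88 ± 0.45 (SD, n = 3) in the MHC II-competent group. The sign of its difference turned under quantile normalization (0.07) and without competent 1 (0.14), competent 2 (0.11) or deficient 3 (0.05). The difference was -0.26 without competent 3, and -0.48 with the myeloid score as a covariate (SE 0.20, adjusted p = 0.31). Of 17 suppressive effector genes, 4 fell and 0 rose (9 lower adjusted over the list alone). Il10, the gene of the inhibitory cytokine interleukin-10, fell by 1.42 (SE 0.15, adjusted p = 0.0021), Prdm1, which encodes the transcription factor Blimp-1, by 0.87 (SE 0.16) and Fgl2, a secreted effector of Tregs, by 0.64 (SE 0.11), and Tigit is a member here too. The medians were -0.32 and -0.33. Camera called both lists (adjusted p = 4.26e-05 and 2.09e-06), with adjusted p = 0.17 and 0.13 with an estimated correlation, and fry gave 0.051 and 0.015. Treg identity shares 10 of its 21 genes with other lists, and without shared genes its adjusted p was 0.061 (5.18e-07 to 0.17 over the alternatives). The myeloid list stood at a median of 0.71, and each of the 2 lists had 2 lower genes past the threshold once the myeloid score was a covariate. Both medians were then -0.45 (adjusted p = 5.18e-07 and 4.82e-06), and the median SE went from 0.15 to 0.20 for identity and from 0.12 to 0.18 for effector genes. The identity count was 2 without competent 2 and 7 without competent 3, and the effector count 1 without competent 2 and 2 without deficient 2. Calls ended for Nrp1 without any array but competent 3 (highest adjusted p 0.18), for Tigit without competent 2 (0.068), for Prdm1 without competent 1 and 2 and deficient 2 (0.091) and for Fgl2 without competent 2 and deficient 1 and 2 (0.066).

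Genes that T cells induce on TCR stimulation were mixed. Of 28 tested, 4 fell and 1 rose (6 lower and 2 higher adjusted over the list alone). Egr2, an early growth response transcription factor, fell by 1.41 (SE 0.15, adjusted p = 0.0027), Irf4 by 0.89 (SE 0.12, adjusted p = 0.0066), Nab2, a cofactor of the Egr proteins, by 0.52 (SE 0.11, adjusted p = 0.038) and Nr4a1, the gene of the receptor Nur77, by 0.51 (SE 0.11, adjusted p = 0.042). Jun rose by 0.70 (SE 0.11, adjusted p = 0.012). Cd5 stood at -0.26 (SE 0.13, adjusted p = 0.30). The median was -0.13, with a camera adjusted p of 0.031 and an adjusted p = 0.26 with an estimated correlation. It was -0.069 without competent 1, -0.090 without deficient 3 and -0.082 under quantile normalization. That call was also lost with a filter at the median (0.26), median centring (0.057) and lists without shared genes (0.061), and without competent 1 (0.053), competent 2 (0.061) or deficient 3 (0.058), and the adjusted p over the alternatives ran from 0.0059 to 0.26. Egr2 and Irf4 stayed past the threshold without each single array and with the myeloid score as a covariate (myeloid median 0.71). That covariate ended the calls of Nab2 (-0.43, SE 0.17), Nr4a1 (-0.47, SE 0.17) and Jun (0.62, SE 0.17). Their SE went from 0.11 to 0.17, and their differences also shrank. The count of lower genes was 2 without competent 1, competent 2, deficient 1 or deficient 3. The calls of Nr4a1 and Nab2 ended without any array but competent 3 (highest adjusted p 0.15 and 0.13), and that of Jun without deficient 1 or 2 (0.063). The genes of the TCR complex and its proximal signalling were not called as a list (median -0.05, adjusted p = 0.69, with the sign turned to 0.01 under quantile normalization and to 0.0035 without competent 1). Of 19 tested, Themis, which tunes TCR signalling, was the 1 past the threshold (0.47, SE 0.10, adjusted p = 0.040; 1 adjusted over the list alone), and its call ended without any single array (highest 0.14) and with the covariate (0.52, SE 0.16).

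Genes of naive and quiescent T cells lay higher, with 4 of 16 past the threshold and 0 lower (9 and 0 adjusted over the list alone). Dapl1, a gene of unsettled function in T cells, was 3.90-fold higher (log2 1.96, SE 0.23, adjusted p = 0.0032), and the transcription factor genes Bach2 (0.66, SE 0.11) and Foxp1 (0.44, SE 0.09) and the antiproliferative gene Btg1 (0.56, SE 0.12) rose as well. Klf2, a transcription factor of lymphocyte trafficking, stood at 0.10 (SE 0.12, adjusted p = 0.70; 0.030 without deficient 2, 0.19 without deficient 1). The median was 0.32, with a camera adjusted p of 1.32e-06 and an adjusted p = 0.12 with an estimated correlation. Among 7 markers of conventional CD4 T cells, the CD4+ T cells that are not Tregs, 3 rose and 0 fell (3 and 0 adjusted over the list alone). They were Dapl1, Pde3b, a phosphodiesterase gene (1.27, SE 0.12), and Tnfsf8, which encodes the CD30 ligand (0.88, SE 0.12). That list had a median of 0.27 (adjusted p = 0.00065, and adjusted p = 0.11 with an estimated correlation). Over the alternatives its median ran from 0.07 to 0.57. Once the myeloid score was a covariate, 0 of the naive genes and 2 of the conventional markers passed, beside a myeloid median of 0.71. The naive median went from 0.32 to 0.25 (13 of 16 genes higher, adjusted p = 0.0036) and the conventional median from 0.27 to 0.07 (adjusted p = 0.015), while the median SE went from 0.11 to 0.16 and from 0.12 to 0.18. The naive count was 1 without competent 1, deficient 1 or deficient 2, and 2 without competent 2 or deficient 3. The call of Foxp1 ended without any array but competent 3, that of Btg1 without any but competent 2 (highest adjusted p 0.16 for both), and that of Bach2 without competent 1 and 2 and deficient 1 and 2 (0.078).

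Cell cycle genes were lower. Of 23 tested, 22 lay lower, 8 fell and 0 rose (13 lower adjusted over the list alone). The mitotic kinesin gene Kif11 fell by 0.73 (SE 0.11, adjusted p = 0.012), the centromere gene Cenpe by 0.65 (SE 0.12), the replication licensing gene Mcm3 by 0.56 (SE 0.09) and the cyclin gene Ccne2 by 0.53 (SE 0.11). The median was -0.42, with a camera adjusted p of 6.34e-11 and an adjusted p = 0.15 with an estimated correlation. It was -0.27 without competent 1 and -0.52 without competent 3. The myeloid list stood at 0.71, and 0 of the 23 genes passed once its score was a covariate. The list median was -0.42 without and with the score (22 of 23 genes lower, adjusted p = 6.70e-10 with it), and the median SE went from 0.12 to 0.17 with 3 residual degrees of freedom. The count of lower genes was 4 without competent 1, 0 without competent 2, 0 without deficient 1, 1 without deficient 2 and 5 without deficient 3. The call of Kif11 ended without competent 2 or deficient 1 (highest adjusted p 0.063), that of Cenpe without competent 2, deficient 1 or deficient 2 (0.098), that of Ccne2 without competent 2 or any deficient array (0.12) and that of Mcm3 without any array but competent 3 (0.068).

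Lists of metabolism and biosynthesis held 0 genes past the threshold, over all genes and adjusted over the list alone. All 17 genes of mitochondrial respiration lay lower (median -0.18, adjusted p = 0.00085), as did 17 of 19 genes of the nucleolus and ribosome biogenesis (median -0.21, adjusted p = 0.00090). The adjusted p = 0.36 and 0.38 with an estimated correlation, and fry gave 0.15 and 0.17. Beside a myeloid median of 0.71, the medians were -0.25 and -0.24 with the myeloid score as a covariate (17 of 17 and 19 of 19 genes lower, 0 past the threshold). Under quantile normalization 13 of the 17 respiration genes lay lower (median -0.10), and 13 without competent 1. Glycolysis (13 genes, median -0.14, adjusted p = 0.077) and cholesterol and fatty acid synthesis (16 genes, median 0.10, adjusted p = 0.14) were not called. Glycolysis was called in 4 of 18 alternatives, and cholesterol synthesis in 3. Glycolysis stood at -0.090 without competent 1, and cholesterol synthesis at -0.0085 without competent 3 and 0.17 without competent 2. The 14 IL-2 and STAT5 targets, which report signalling through the receptor that CD25 belongs to, stood at a median of 0.06 (adjusted p = 0.33, 0 past the threshold by either adjustment), and 10 heat shock genes at -0.10 (adjusted p = 0.33, 0 past over all genes and 1 lower adjusted over the list alone; fry gave 0.037, and the alternatives ran to 0.66). Without competent 3, 1 lower gene passed in each of the glycolysis, respiration and nucleolus lists, and without competent 1, 1 lower gene of the IL-2 list, whose median was 0.10 there and 0.016 without competent 3. The heat shock median was -0.049 without competent 2.

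In the TNF receptor family and NF-kappaB list, Icos and Tnfrsf1b, which encodes TNF receptor 2 (-0.75, SE 0.12, adjusted p = 0.013), fell among 15 genes (5 lower and 2 higher adjusted over the list alone). The median of this list was 0.07 (0.14 without competent 1, 0.0385 without competent 3), while its mean was -0.08 and camera's direction was down (adjusted p = 0.81). The call of Tnfrsf1b ended without competent 2 or deficient 1 (highest adjusted p 0.066) and that of Icos without competent 1, competent 2 or deficient 2 (0.089), while without competent 3 there were 4 lower genes. Among 14 apoptosis regulators Fasl, the Fas ligand gene, was the 1 past the threshold (0.66, SE 0.09, adjusted p = 0.0066; 1 higher and 1 lower adjusted over the list alone). Here the median was 0.01 (-0.055 without competent 1, 0.040 without deficient 2), the mean -0.02, and camera pointed down and fry up, with neither calling the list (adjusted p = 0.81 and 0.84). In the helper lineage list of 12 genes, Il17a (-0.81, SE 0.16, adjusted p = 0.030) and Il17f (-0.64, SE 0.12, adjusted p = 0.022), the interleukin-17 genes, fell and Tbx21, the Th1 transcription factor gene, rose (0.51, SE 0.09, adjusted p = 0.017). The list had 3 lower and 2 higher members adjusted over the list alone and was not called (median -0.06, with -0.13 without competent 2 and -0.0074 without deficient 3, adjusted p = 0.47). Beside a myeloid median of 0.71, 0 genes of the TNF receptor, apoptosis and helper lists passed once the myeloid score was a covariate. Tnfrsf1b went from -0.75 to -0.62 (SE 0.12 to 0.17), Icos from -0.70 to -0.77 (0.13 to 0.19), Fasl from 0.66 to 0.70 (0.09 to 0.14), Tbx21 from 0.51 to 0.51 (0.09 to 0.14), Il17a from -0.81 to -0.84 (0.16 to 0.24) and Il17f from -0.64 to -0.48 (0.12 to 0.17), so the SE grew for all 6 while the differences of Tnfrsf1b and Il17f also shrank. The 3 calls of helper genes ended without several arrays: Il17a and Tbx21 without any array but competent 3, and Il17f without competent 1 and each deficient array (highest adjusted p 0.11, 0.080 and 0.085).

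Markers of other lymphocytes and of blood cells were also followed. All 9 tested CD8 T and NK cell genes lay higher (median 0.39). Klrd1 and Klrc1, which encode the chains of the CD94-NKG2A receptor, rose (2 adjusted over the list alone), and 0 fell. Klrc1 was 3.49-fold higher (log2 1.81, SE 0.33, adjusted p = 0.022). Cd8a (0.32, SE 0.13, adjusted p = 0.21) and Nkg7 (0.41, SE 0.16, adjusted p = 0.20), both chosen after their values were seen, did not pass, and Nkg7 stood at 0.25 without competent 3. Camera called this list (adjusted p = 2.09e-06), with an adjusted p = 0.075 with an estimated correlation. Of 8 B cell genes, Cd22, an inhibitory receptor gene (1.32, SE 0.14, adjusted p = 0.0025), and the adaptor gene Bank1 (1.06, SE 0.24, adjusted p = 0.047) rose and 0 fell (3 higher and 1 lower adjusted over the list alone), with a median of 0.16 (adjusted p = 0.018, and adjusted p = 0.30 with an estimated correlation). The 5 erythroid and platelet genes lay higher with 0 past over all genes and 1 adjusted over the list alone (median 0.19, adjusted p = 0.022, and adjusted p = 0.34 with an estimated correlation). Klrd1 and Cd22 stayed past the threshold without each single array and with the myeloid score as a covariate, while Klrc1 did not pass without competent 2, deficient 1 or deficient 3 (highest adjusted p 0.10) and Bank1 without any array but deficient 3 (0.17). With that covariate Klrc1 stood at 1.49 (SE 0.48, adjusted p = 0.19) and Bank1 at 0.41 (SE 0.21, adjusted p = 0.38), and neither passed; the difference of Bank1 shrank, while its SE was 0.24 before. The B cell call was lost without competent 2 (adjusted p = 0.051) or competent 3 (0.054), with a filter at the median (0.064), quantile normalization (0.0525) and the covariate (0.077). The erythroid call was lost without competent 2 (0.055) or deficient 1 (0.052), with no filter (0.24), a filter at the median (0.10) and fry (0.098). Over the alternatives the adjusted p ran from 0.0016 to 0.30 for B cells and from 0.012 to 0.34 for the erythroid list. The erythroid list had 1 gene past the threshold without competent 3. The B cell median ran from 0.10 to 1.06 over the alternatives, with 3 genes tested under a filter at the median.

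**Figure D3:**
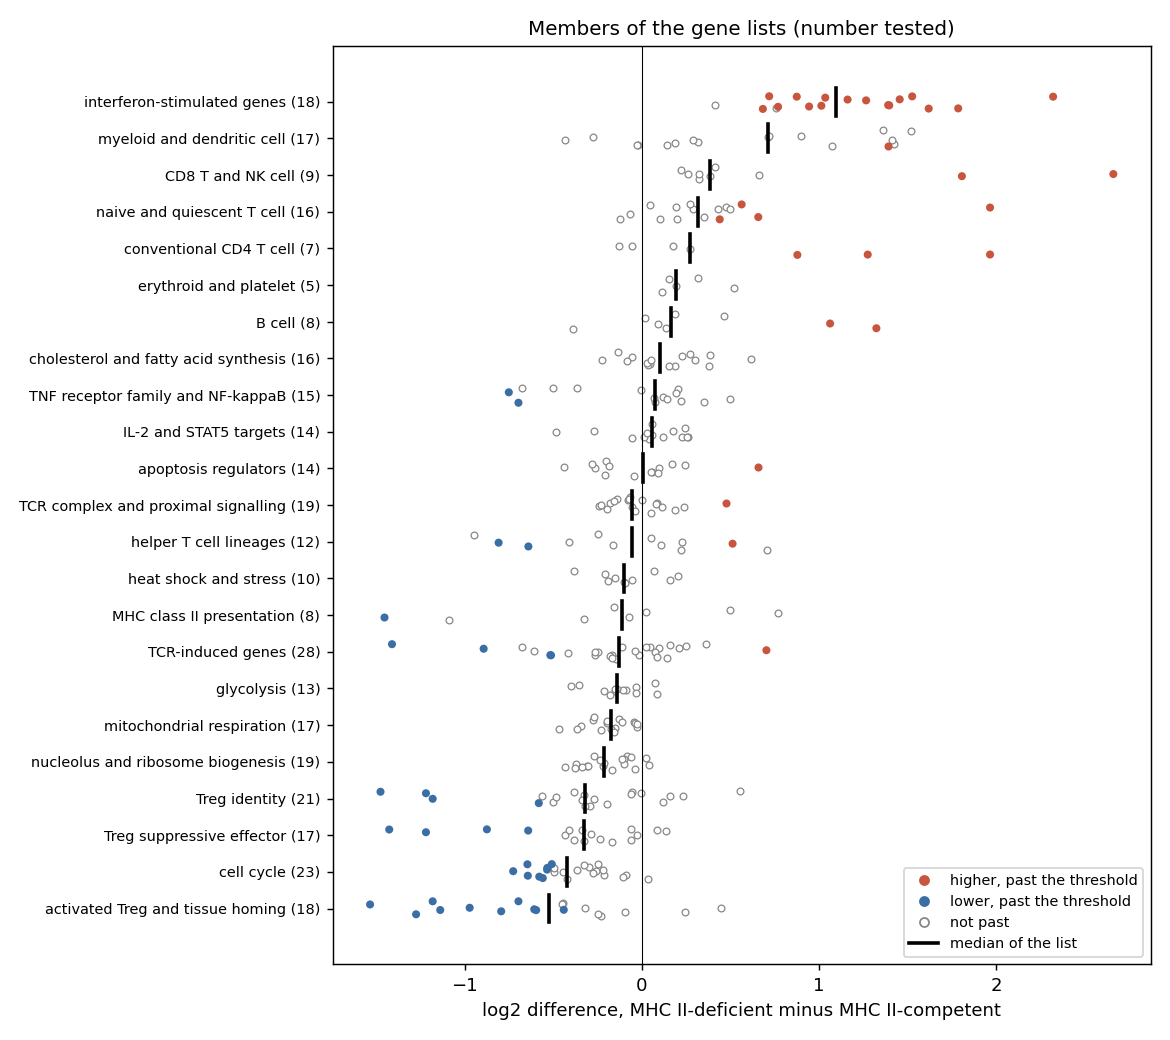
Each row is 1 of the 23 gene lists with its number of tested genes, and each point is a gene placed by its log2 difference (MHC II-deficient minus MHC II-competent); filled points are past the threshold and black bars are list medians. Medians run from -0.52 for activated Tregs and tissue homing to 1.10 for interferon-stimulated genes; the bars of TCR signalling and apoptosis near 0 change sign with the scaling or the test.

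Camera called 14 of the 23 lists, 7 higher and 7 lower. With an estimated correlation 0 were called (lowest adjusted p 0.075; 7 lists had an unadjusted p under 0.05), and fry called 10.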

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

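The probe sets described here entered no named result, and their test, a fit over every probe set of the table, was among those chosen before the data were examined. Of the 5140 probe sets paired with no gene, 34 were higher and 24 lower in the MHC II-deficient group at limma's adjusted p under 0.05. Of the 1321 paired with several genes, 16 were higher and 11 lower. Among those with no gene, the largest increase past the threshold was 3.0 on the log2 scale (row 10502791, SE 0.17, adjusted p = 0.00065), and the largest decrease -2.69 (row 10345762, SE 0.24, adjusted p = 0.0035), both picked after their values were seen. In the same fit, 142 of the 21640 probe sets paired with 1 gene were higher and 164 lower. Those with several genes or none were flagged because the comparison of genes leaves them out. Their share of differences was not tested against that of the probe sets with 1 gene.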

How the results depend on the processing

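The fit with the myeloid score was chosen after the data had been examined. Counts of genes (507, with 201 higher and 306 lower) kept within 1.5 times under no filter, the filter at the median, quantile normalization, the trended robust prior, array weights and the mean of rows. Median centring gave 127 higher genes, all rows 199 lower, an adjusted p under 0.1 946 (363 and 583), a minimum of 1.5-fold 329 (187 lower) and the myeloid score 102 (45 and 57). The limits on p and fold change the counts by construction; elsewhere the cause was not tested. With 1 array left out, and so fewer samples, the counts ran from 159 to 708 (76 to 222 higher, 81 to 486 lower) and lists from 12 to 14 of 23. An estimated correlation called 0 lists against 14. The labels do not say whether the replicate numbers pair the arrays. Deviations of same-numbered arrays correlated at -0.02, -0.14 and 0.07, which shows no clear pairing but cannot exclude one. With the replicate block, 564 genes passed, 422 of them among the 507. Of 58 named genes past the threshold, 24 stayed past under every alternative run for them and 0 changed sign. Signs turned only for values short of the threshold, except for the test direction of the called myeloid list once its own score was a covariate. The filter at the median turned the test direction of TCR signalling (median -0.054), TNF receptor (0.075) and helper (0.14) lists; quantile normalization that of TCR signalling (0.014), TNF receptor (0.11) and apoptosis (0.018) lists, Foxp3 (0.017), Gzma (0.045, against -0.03) and Tnfrsf18 (0.065); array weights and fry that of apoptosis (0.015 and 0.0051); lists without shared genes that of TNF receptor (0.14); and the myeloid score that of cholesterol synthesis (-0.14), H2-DMa (from 0.50 to -0.14) and Gzma (0.15), all with causes not tested. By construction that score also took the difference from its own list (test direction turned, median from 0.71 to 0.064) and from Mpeg1 (1.42 to -0.28) and Csf1r (0.89 to -0.15). Mpeg1, Csf1r, Gzma and H2-DMa were named after their values were seen. Leaving out arrays moved TNF receptor from 0.0385 to 0.14, apoptosis from -0.055 to 0.040, cholesterol synthesis from -0.0085 to 0.17, Gzma from -0.22 to 0.18 and Tnfrsf18 from -0.26 to 0.14.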

Other observations

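The family scan and the tests of explanations below were chosen after the results were seen; the counts over other splits of the arrays were planned.

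Gene families named by symbol, some of them overlapping the fixed lists (Kif11 and Kif20a are cell cycle genes), were scanned. Of 227 groups of 8 to 100 tested genes sharing the letters of their symbol, 24 were called by camera and 0 with an estimated correlation, where 12 had an unadjusted p under 0.05. The 5 families described below were picked from the 24. Camera also called the Ccr genes lower (4 of 8 fell, median -0.63, adjusted p = 0.00094). It called families with 0 genes past the threshold too, such as Krtap (median 0.14, adjusted p = 0.010), Prss (0.11, adjusted p = 0.024) and Eif (-0.12, adjusted p = 0.0068). A camera call of a small median is therefore weak evidence for a family. Among 8 guanylate binding protein genes, interferon-inducible GTPases of host defence, 6 rose and 0 fell (median 0.72, adjusted p = 4.21e-08, and adjusted p = 0.59 with an estimated correlation). Gbp9 (9.93 to 10.93) and Gbp4 (log2 difference 0.83, SE 0.10) were among them, both, as Parp12, Parp1 and Slfn5, named after their values were seen. Of 11 Parp genes 6 rose, with Parp12 at 1.08 (SE 0.15), while Parp1, a DNA repair gene, fell by 0.63 (SE 0.11), with a median of 0.49 (adjusted p = 0.00099, and 0.59 with an estimated correlation). Of 9 Slfn genes 3 rose, with Slfn5 at 0.96 (SE 0.15, median 0.27, adjusted p = 0.0039, and 0.76 with an estimated correlation). Among 36 kinesin genes 6 fell (median -0.11, adjusted p = 0.0024, and 0.59 with an estimated correlation), and 28 mitochondrial ribosomal protein genes of the small subunit lay at a median of -0.22 with 0 past the threshold (adjusted p = 0.00040, and 0.75 with an estimated correlation). The 5 medians kept their sign under quantile normalization and median centring. The kinesin median was -0.07 without deficient 3 and -0.30 with a filter at the median, and that of the mitochondrial ribosomal proteins -0.14 under quantile normalization. Kinesin calls numbered 2 without competent 1, 0 without competent 2 or deficient 1 and 1 without deficient 2. Gbp calls numbered 3 without competent 1 or deficient 3 and 2 without competent 2 or deficient 1, and Parp increases 2 or 3 without any array but competent 3. The call of Parp1 ended without competent 1, competent 2 or deficient 1 (highest adjusted p 0.072) and that of Slfn5 without competent 2 or deficient 1 (0.068), where 1 Slfn gene passed without deficient 1. Once the myeloid score was a covariate, 2 Gbp genes and 0 Parp, Slfn and kinesin genes passed. The medians went from 0.72 to 0.81 (Gbp), 0.49 to 0.48 (Parp), 0.27 to 0.16 (Slfn) and -0.11 to -0.17 (kinesins), and the median SE from 0.13 to 0.17, 0.11 to 0.16, 0.11 to 0.17 and 0.12 to 0.17.

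Single genes of immune function, chosen after their values were seen, stood out as well. The chemokine gene Cxcl10 (1.39, SE 0.15), the costimulatory ligand gene Cd86 (1.10, SE 0.13), Slamf7 (1.47, SE 0.17), Jaml (1.38, SE 0.16) and the RNA sensor gene Tlr7 (0.92, SE 0.11) rose and stayed past the threshold without each single array. Timp2 (-1.25, SE 0.09), the fatty acid binding protein gene Fabp5 (-1.18, SE 0.10) and the transcription factor gene Nfil3 (-1.02, SE 0.10) fell and did so too. With the myeloid score as a covariate, Cd86 and Jaml no longer passed (adjusted p = 0.068 and 0.059, from 0.0021 and 0.00092 over the alternatives), as the difference went from 1.10 to 0.91 and from 1.38 to 1.11 and the SE from 0.13 to 0.18 and from 0.16 to 0.21.

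The 6 arrays split into 3 and 3 in 10 ways, which cannot give a share under 0.05. The real split gave 507 genes, and the highest of the others 0. For the lists, the real split gave 14 and the highest other 10. In each case 1 split, the real one, gave as many.

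The higher interferon-stimulated genes were weighed against macrophage RNA and against a shift of whole arrays. With the myeloid score as a covariate the median log2 difference of the 18 genes was 1.06, against 1.10 without it. All 18 stayed higher, which argues against the amount of macrophage RNA as the whole source. The score follows amount only, so it cannot test macrophages that differ in interferon-stimulated genes between the recipients. The number of the 18 genes past the threshold went from 16 to 11 as the median SE went from 0.12 to 0.18. The score differs between the groups and leaves 3 residual degrees of freedom. A shift of whole arrays moves genes together, but the activation and homing list lay at -0.52 in the same arrays, while the median over all tested genes, 0.02, decides nothing here, since RMA holds it near 0. The lack of MHC class II in the recipients, the difference the design names, stays open and untested, as does RNA of a cell type that the myeloid list does not follow.

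H2-Ab1 and H2-Aa lay lower beside Cd74, and fewer antigen-presenting cells in the MHC II-deficient sort would lower Cd74 and the myeloid genes too, but Cd74 stood at 0.77 (0.54 to 1.05 with 1 array left out) and the myeloid list at 0.71 (0.42 to 0.88, and 0.30 with no filter). Per array, H2-Ab1 minus Cd74 was -0.25, -0.22 and -0.44 in the MHC II-competent and -2.79, -2.43 and -2.36 in the MHC II-deficient group (difference -2.22, SE 0.15, exact permutation p = 0.10, two-sided, the smallest that 3 against 3 allows). The slope of H2-Ab1 on the myeloid score was 1.60 over the MHC II-competent and 0.22 over the MHC II-deficient arrays, a test that replaced an earlier, void one. It decides nothing, since each slope rests on 3 arrays and H2-Ab1 lay at 5.70 in the MHC II-deficient group, near the filter value of 5.205. RNA of recipient cells therefore stays open, and which class II genes the MHC II-deficient recipients lack is not given in the sources used here.

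The lower activation and homing genes were weighed against fewer Tregs in the sort and against macrophage RNA, over all 18 genes of the list, since an earlier form of the tests used the 10 that fell and so were chosen for the pattern. The 95% interval of the Foxp3 difference starts at -0.27, above the list median of -0.52 (-0.57 to -0.48 with 1 array left out). For Foxp3 alone this argues against an even dilution of Tregs by other cells as the whole cause. Il2ra (-0.27), Ctla4 (-0.33) and Ikzf2 (-0.29) lay lower without passing, and Tnfrsf18 stood at -0.00. The Treg identity list had a median of -0.32 (17 genes lower, 4 higher), and that of conventional CD4 T cells 0.27 (5 higher, 2 lower). A dilution that accounts for part of the fall therefore stays open. Foxp3 cannot show which Tregs, or which other CD25+ T cells, were sorted, so a change in their make-up was not tested. With the myeloid score as a covariate the list median was -0.57 and 16 of the 18 genes lay lower. This argues against the amount of macrophage RNA as the whole cause. However, 1 gene was past the threshold against 10 before, as the median SE went from 0.12 to 0.17 with 3 residual degrees of freedom. The lack of MHC class II in the recipients, which the design names, stays open and untested.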
